A study of Mus musculus with 40 samples.

How the data were processed

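The deposited table gives 1 value per annotated repeat copy and library, and its unit is called signal here: the authors divided whole reads by 1 factor per library, which the values themselves show, since every value of a library was a whole multiple of that library's smallest value (within 0.1 of a read for 100% of values). The reads were recovered by that division. The value of 1 read lay between 0.659 and 1.51 across the 40 libraries. How the factors were computed is not given in the sources used here, and they lay between 0.843 and 1.12 of the factors that a median of ratios gives on the same table. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the mouse build mm10 without saying which step each served. The repeat annotation and the treatment of reads that map to several copies are not given in the sources used here.

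Loci are single repeat copies, and subfamilies are sums of the linear signal of all copies with the same repeat name; a copy with a compound name was added to the internal part it names, or else to its first name. Loci and subfamilies with a mean signal of at least 5 over all libraries were tested, 33215 of 835636 loci and 1004 of 1237 subfamilies. The tested loci held 83.7% of the signal. Differences were tested on log2(signal + 1) with limma 3.58.1 in R 4.3.3 (1 mean per group over all 11 groups, trended prior, two-sided), with Benjamini-Hochberg adjustment within each comparison and a call at an adjusted p under 0.05. Log2 fold changes are limma estimates and SE is their standard error. Lists of subfamilies, fixed by repeat name, were tested with camera (limma, correlation preset to 0.01) and adjusted over 112 tests; the lists are IAP, ETn/MusD, MMERVK10C, MuLV, VL30, MERVL, MaLR, young L1, older L1, B1 SINE, B2 SINE, B4 SINE, MIR, L2, DNA transposons and Satellites, with levels alone for MMTV. With an estimated correlation every list in every comparison had adjusted p = 0.984. Alternatives used TMM factors, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, among others.

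The places of copies relative to genes come from GENCODE release M21 (GRCm38) by overlap with bedtools 2.31.1; exons took precedence over introns. Coordinates are those of mm10. For host genes the signal of exon copies was summed per gene and tested in the same way. Chromosome shifts are medians, over the exon copies of a chromosome with a mean signal of at least 20, of the deviation of log2 signal from its mean over all libraries, taken relative to the median chromosome of the library. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Shares are percentages of a library's signal over all 835636 copies, and tests of shares are exact two-sided permutation tests.

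The comparisons, filters, lists and the rule for named features were set before the data were examined. For each comparison the rule takes the 8 highest and 8 lowest log2 fold changes among called subfamilies, the 5 highest and 5 lowest among called loci whose groups do not overlap in signal, and the 2 to 4 members of each list with the highest mean. IAPEz-int, MMVL30-int, RLTR4_MM-int, MERVL-int, B1_Mm and B2_Mm2 are described in every group. One locus taken by the rule and one host gene are not reported here. L1Md_T and L1Md_A were not analysed here under those names. The young L1 list, matched on the start of the name with case ignored, also took in 6 older L1MD names. The MaLR list, matched in the same way on starts that include MLT, also took in names beginning with MLTR or MLT2. Whether these belong to the MaLR family was not checked. A fold against a group with signal 0 in every library is a lower bound computed against a floor of 3 reads per library; floors cover counting error only. In simulated data with known changes of 4-fold, the test called between 28.8% (Balb/c-1 against N2.3, and CBA against Balb/c-2 rep2) and 48.5% (F2 against F0) of the changed loci, and of 2-fold changes between 1.49% and 10.4%. Each share rests on 66 (4-fold) or 67 (2-fold) changed loci among 33215, most of which were left unchanged. In the real data up to 3222 loci were called, so the shares do not give the power of the real comparisons.

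The labels name a first sequencing batch of 2021, a second of 2022 and a resequencing of the F2 cells in 2022. They do not assign libraries to these or say which run the F2 values come from, so batch was not a term of the model. Letters name different tumours and pair samples in Balb/c-2 and Balb/c-2 rep2 alone, where deviations from the group mean correlated at 0.155 to 0.255 across loci for the same letter and at -0.195 to -0.0563 for other letters.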

Results

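Poly(A) RNA was sequenced from YUMM1.7, a melanoma line derived from C57BL/6 mice, and from cells grown out of tumours of its serial passages through mice. Signal was measured at single annotated repeat copies. The 40 libraries form 11 groups. They are YUMM1.7 cells (n = 3), F0 (n = 4), F1 (n = 4), F2 (n = 5), N2.1 (n = 5), N2.2 (n = 3), N2.3 (n = 3), Balb/c-1 (n = 4), Balb/c-2 (n = 3), repeat libraries of the same Balb/c-2 tumours (Balb/c-2 rep2, n = 3) and CBA (n = 3). Letters name different tumours of a passage, whose cells had been cultured for 1 to 3 passages. Balb/c and CBA are names of inbred mouse strains, and what N2 stands for is not given in the sources used here. The 3 YUMM1.7 libraries are cultures of 1 line. Their spread covers these cultures and no wider population. Each passage likewise occurs once in the series, so p-values cover the spread between its tumours and not a repeat of the passage.

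Recovered reads in repeat copies lay between 1280522 and 2976730 per library. They were 1709100 to 1861048 in YUMM1.7 cells, 1699060 to 2050776 in F0, 1502938 to 1935341 in F1 and 1619774 to 2001795 in F2. In the N2 groups they were 1817555 to 2575221 (N2.1), 1901295 to 2976730 (N2.2) and 2272989 to 2507112 (N2.3). They were 1821695 to 2342103 in Balb/c-1, 1690015 to 1873914 in Balb/c-2, 1280522 to 1761884 in Balb/c-2 rep2 and 1682589 to 1771698 in CBA. Copies in 3' UTRs held 54.5% of the signal of tested loci, copies in coding exons 14.4%, copies in introns 12.1% and intergenic copies 6.24%. Most of the signal was therefore in repeat copies that are part of host gene exons.

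Scaling by TMM in place of the deposited factors moved the median log2 fold change of all loci. It went from 0.13 to 0.01 for F0 against YUMM1.7 cells, from -0.12 to -0.02 for F2 against F0 and from 0.26 to 0.07 for N2.1 against F2. It went from -0.17 to -0.03 for Balb/c-1 against N2.3 and from 0.20 to 0.09 for CBA against Balb/c-2 rep2. The bulk of loci thus moved by up to these medians with the scaling alone.

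MMVL30-int, the internal part of VL30 (a retrovirus-like element without its own protein genes), varied between groups and between tumours of a group. Its summed signal (mean ± SD, n as above) was 22460 ± 1577 in YUMM1.7 cells, 13952 ± 3802 in F0, 19616 ± 9194 in F1 and 24924 ± 11907.5 in F2. It was 14651 ± 7339 in N2.1, 27899.8 ± 3927 in N2.2 and 31435 ± 10004 in N2.3. MMVL30-int had 12498 ± 2571 in Balb/c-1, 23613 ± 14604 in Balb/c-2, 23784 ± 15424 in Balb/c-2 rep2 and 8508 ± 309.9 in CBA. IAPEz-int, of the intracisternal A particle family of endogenous retroviruses, had 7689.6 ± 291 in YUMM1.7 cells, 6380.2 ± 1595 in F0, 6816 ± 907 in F1 and 6468 ± 1336 in F2. It had 8486 ± 1651 in N2.1, 15418 ± 7116 in N2.2 and 12288 ± 3709.8 in N2.3. IAPEz-int had 10158 ± 6606 in Balb/c-1, 7516 ± 2184 in Balb/c-2, 7762 ± 2379 in Balb/c-2 rep2 and 7286 ± 1465 in CBA. It was called in no comparison (limma, smallest adjusted p = 0.204, for N2.1 against F2). RLTR4_MM-int, of the murine leukaemia virus type, had 5085 ± 123 in YUMM1.7 cells, 5136 ± 777 in F0, 6185 ± 606 in F1 and 6385 ± 1228 in F2. It had 6765 ± 850.3 in N2.1, 8198 ± 395 in N2.2 and 9223 ± 1375 in N2.3. RLTR4_MM-int had 8001 ± 620.2 in Balb/c-1, 6634 ± 812 in Balb/c-2, 7656 ± 1069.97 in Balb/c-2 rep2 and 10329.6 ± 973 in CBA.

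MERVL-int, of an endogenous retrovirus active in early embryos, had 964 ± 245 in YUMM1.7 cells, 937 ± 126 in F0, 1043 ± 215 in F1 and 844 ± 132 in F2. It had 1099 ± 114 in N2.1, 1176 ± 46.6 in N2.2 and 1626 ± 477 in N2.3. MERVL-int had 987 ± 98.9 in Balb/c-1, 1024 ± 125 in Balb/c-2, 1150.2 ± 79.1 in Balb/c-2 rep2 and 1286 ± 187 in CBA. B2_Mm2, a short element copied by the L1 machinery, had 27637 ± 2301 in YUMM1.7 cells, 29199.6 ± 2173 in F0, 25799.8 ± 3504 in F1 and 26749 ± 3362 in F2. It had 38013 ± 1505 in N2.1, 40274 ± 209.8 in N2.2 and 38911 ± 3063 in N2.3. B2_Mm2 had 35066 ± 3433 in Balb/c-1, 37809 ± 1713 in Balb/c-2, 29241 ± 1570.2 in Balb/c-2 rep2 and 35044 ± 2981 in CBA. B1_Mm, of the B1 family of short elements, had 17767 ± 836 in YUMM1.7 cells, 16811 ± 668 in F0, 18116 ± 1661 in F1 and 17797 ± 1046 in F2. It had 19803 ± 671 in N2.1, 20147 ± 817 in N2.2 and 19416 ± 730.0 in N2.3. B1_Mm had 18256 ± 727 in Balb/c-1, 18284 ± 749.6 in Balb/c-2, 16679 ± 157 in Balb/c-2 rep2 and 19458 ± 649.5 in CBA. The mouse mammary tumour virus list, MMTV, has 2 members, 1 of them tested, and is given as the sum over its members. It had 61.9 ± 12.8 in YUMM1.7 cells, 78.5 ± 22.6 in F0, 59.9 ± 5.88 in F1, 70.6 ± 28.0 in F2, 107 ± 22.4 in N2.1, 106 ± 12.5 in N2.2 and 236 ± 235 in N2.3, whose mean rests on 1 library (range 99.1 to 507). MMTV had 130.4 ± 31.3 in Balb/c-1, 132 ± 31.1 in Balb/c-2, 118 ± 8.45 in Balb/c-2 rep2 and 77.6 ± 7.504 in CBA.

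**Figure D1:**
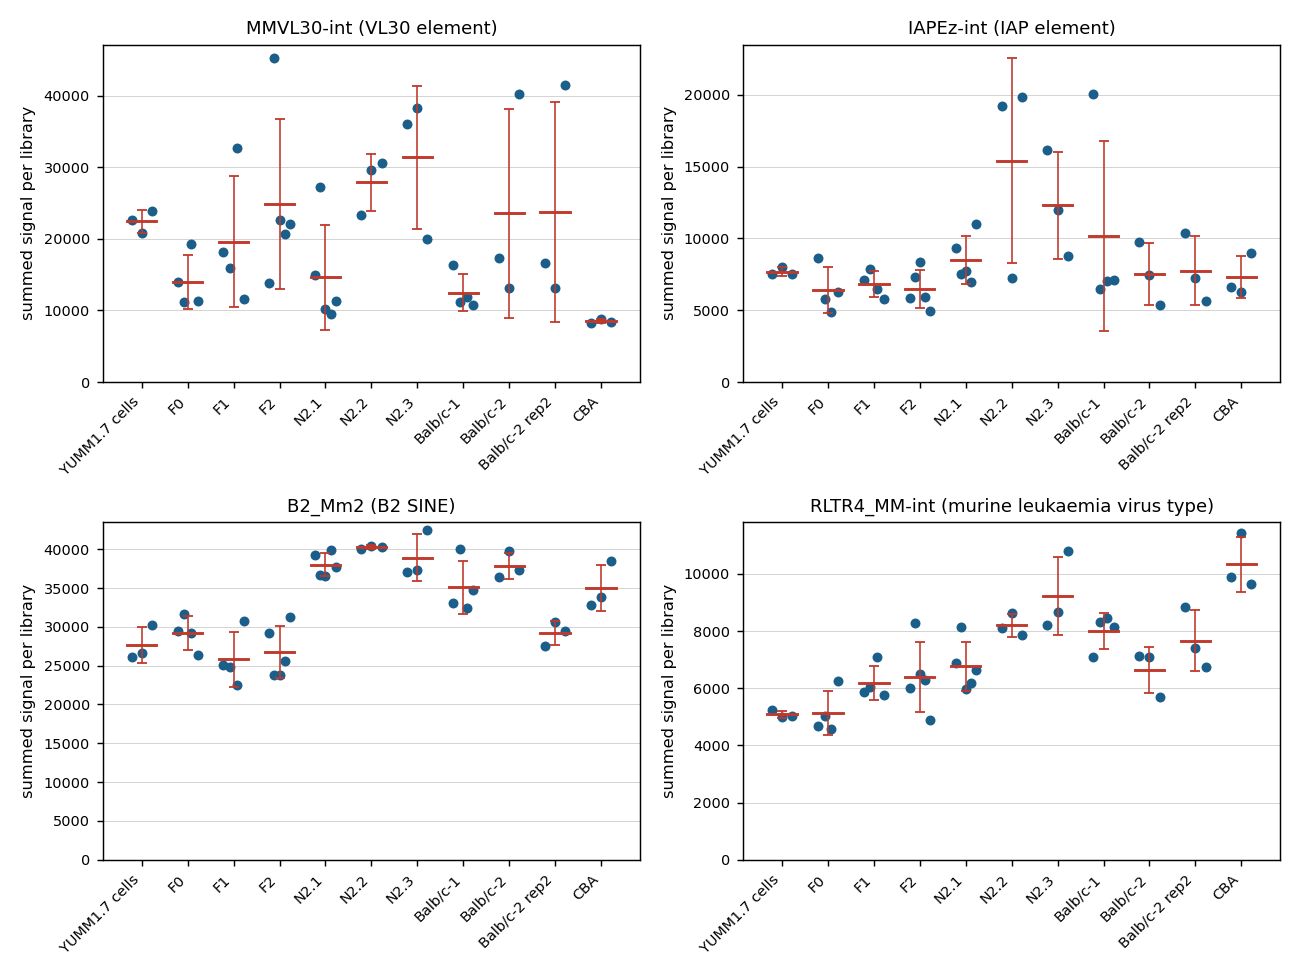
Summed signal of MMVL30-int, IAPEz-int, B2_Mm2 and RLTR4_MM-int per library (dots) in the 11 groups, with the mean (red line) and SD (error bars) of each group. B2_Mm2 lay between 23766 and 31273 in F2 and between 36597 and 39939.8 in N2.1.

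The intron share of the signal, a sign of how much unspliced RNA a library holds, differed between libraries. Its mean was 18.2% ± 1.87 in YUMM1.7 cells, 23.6% ± 1.86 in F0, 17.4% ± 2.95 in F1 and 18.9% ± 4.32 in F2 (SD, n as above). It was 24.8% ± 2.28 in N2.1, 26.0% ± 0.766 in N2.2 and 23.8% ± 2.44 in N2.3. It was 20.4% ± 2.86 in Balb/c-1, 20.6% ± 3.15 in Balb/c-2, 18.4% ± 0.949 in Balb/c-2 rep2 and 25.9% ± 1.38 in CBA. In exact two-sided permutation tests over the 7 comparisons the smallest p was 0.0397, for N2.1 against F2. None passed after Benjamini-Hochberg adjustment (0.181 for that comparison). The smallest p that these permutation tests can give is 0.00794, so 1 comparison alone could not have passed over 7.

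**Figure D2:**
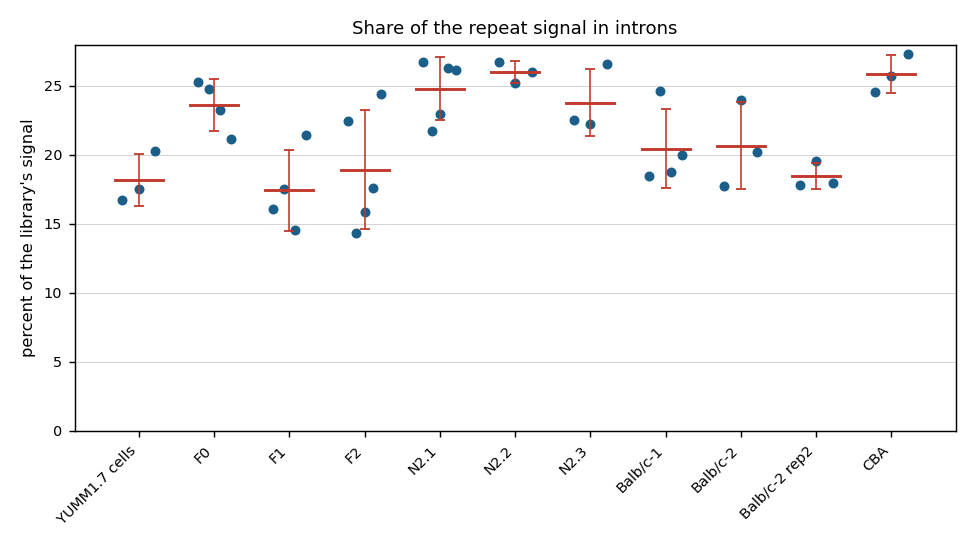
Percent of each library's repeat signal that lay in introns (dots), with the mean (red line) and SD (error bars) of each of the 11 groups. CBA libraries lay between 24.6% and 27.3%, all above the Balb/c-2 rep2 libraries at 17.8% to 19.5%.

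F0 against YUMM1.7 cells asks what changed when the cultured line first grew as tumours. MMVL30-int had a mean of 13952 ± 3802 in F0 (n = 4) against 22460 ± 1577 in YUMM1.7 cells (n = 3). The difference did not pass (limma log2 fold change -0.72, SE 0.37, adjusted p = 0.498). B1 SINE subfamilies were lower in F0 as a list (camera adjusted p = 0.0468; adjusted p = 0.984 with an estimated correlation). Their median log2 fold change was -0.03, and 0 of 15 members were called over all subfamilies or adjusted over the list alone. Summed over copies outside exons the direction of the B1 list was up (adjusted p = 0.00446). IAP, young L1, older L1, MaLR and the other lists had no called member. Adjusted over the list alone older L1 had 1 and MIR 2. Intron copies had a median log2 fold change of 0.39 and 3' UTR copies of -0.12, with an intron share of 23.6% in F0 and 18.2% in YUMM1.7 cells. By limma 0 loci and 0 subfamilies passed, while 2854 loci and 104 subfamilies had an unadjusted p under 0.05. edgeR called 1 locus and 0 subfamilies, and DESeq2 7 loci and 1 subfamily. Leaving out YUMM1.7 culture 3, F0 A or F0 C gave 2, 6 or 1 loci, and leaving out F0 A or F0 B gave 1 subfamily.

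F2 against F0 asks what changed over the F passages. A pair of adjoining copies of leukaemia virus type in an intron of Camk2b, a calcium-dependent protein kinase gene, rose together. Their ends overlap, and whether they are parts of 1 element was not tested, so they do not count as independent results. RLTR4_MM-int (11:6008771-6011515) rose from 103 ± 57.2 in F0 (n = 4) to 651 ± 269 in F2 (n = 5; log2 fold change 2.68, SE 0.47, adjusted p = 0.0379). MuLV-int (11:6005652-6008773) rose from 97.6 ± 45.01 to 564 ± 263 (log2 fold change 2.50, SE 0.48, adjusted p = 0.0387). An intergenic VL30 copy (13:68232872-68237015) rose from 1.64 ± 1.66 to 26.4 ± 12.0. RLTR20A4 in the 3' UTR of Hspb7, a small heat shock protein gene (4:141424729-141424881), rose from 25.7 ± 19.4 to 162 ± 96.3. B1_Mus1 in the 3' UTR of Tbx20, a T-box transcription factor gene (9:24723767-24723915), rose from 45.5 ± 30.1 to 137 ± 44.1. The 2 loci that fell were B2_Mm1a in an intron of Luc7l2 (6:38561246-38561431; 7.002 ± 1.37 to 0.574 ± 0.831) and PB1D9 in a noncoding exon of Etnk1 (6:143188765-143188874; 11.3 ± 5.17 to 2.36 ± 1.81).

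Among subfamilies of F2 against F0, MLTR18B_MM rose from 2107 ± 66.3 to 2959 ± 178 (adjusted p = 0.0178), a direction that turned over copies outside exons (log2 fold change -0.60). The DNA transposon Tigger1 fell from 209 ± 30.1 to 126 ± 20.03 (adjusted p = 0.0372). Of the lists, MaLR had 1 member higher (MLTR18B_MM, in the list only by the start of its name) and DNA transposons 1 lower. Adjusted over the list alone these had 1 each, older L1 2, and MuLV, young L1, B4 SINEs and Satellites 1 each. The intron share was 23.6% in F0 and 18.9% in F2, and intron copies had a median log2 fold change of -0.35 against 0.07 for 3' UTR copies. By limma 13 loci passed (11 higher, 2 lower) and 2 subfamilies. Leaving out F0 A, F0 B, F0 C, F0 D, F2 A, F2 B, F2 D or F2 E gave 48, 0, 5, 2, 0, 3, 1 or 42 loci, and leaving out F0 A, F0 B, F0 C, F0 D, F2 A, F2 B, F2 C or F2 D gave 0, 0, 1, 4, 4, 0, 1 or 0 subfamilies. Each of the 9 features named for this comparison lost its call without at least 4 of the 9 libraries in turn (adjusted p up to 0.299).

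N2.1 against F2 compares the first N2 passage with the last F passage, and single copies rose from near 0 or fell to near 0 between them. RLTR45-int (18:18830966-18836321) rose from 0.182 ± 0.407 in F2 (n = 5) to 56.5 ± 28.1 in N2.1 (n = 5; log2 fold change 5.51, SE 0.48, adjusted p = 9.6e-11). L1Lx_IV on the same chromosome (18:18796568-18797850) rose from 0.783 ± 0.808 to 73.5 ± 28.3 (5.43, SE 0.44, adjusted p = 1.54e-11), and both are intergenic. An intergenic IAP copy (IAP1-MM_I-int, 15:19647741-19650047) with 0 in every F2 library had 51.1 ± 33.3 in N2.1, at least 17.3-fold higher. B1_Mus2 in an intron of Gm20388 (8:123051143-123051291) was likewise 0 in F2 and had 82.5 ± 53.7, at least 27.9-fold higher. L1MdF_IV in an intron of Gm11884 (4:23381829-23387942) rose from 1.53 ± 1.08 to 137 ± 109.997. Before F2 it varied between tumours, with 0 in F0 C and F1 E but 43.9 in F0 A and 29.3 in F1 B. Copies in host genes fell as well. Lx8 (2:10252533-10252873) and B1_Mur2 (2:10254836-10254962) lie in the 3' UTR of Itih5, a gene of the hyaluronan-binding inhibitor family, and fell from 95.6 ± 79.4 to 0.504 ± 1.13 and from 79.2 ± 68.5 to 0.540 ± 0.775. Before F2 these copies also varied between libraries. Lx8 ranged from 0 in F0 B, F0 C, F1 A and F1 E to 497 in YUMM1.7 culture 3. B1_Mur2 ranged from 0 in F0 C, F1 A and F1 E to 430 in the same culture. MER20 in an intron of Rasgrf1, an imprinted gene of a Ras activator (9:90017589-90017753), fell from 59.3 ± 41.1 to 0.336 ± 0.751. RMER6D in the 3' UTR of the prostaglandin F receptor gene Ptgfr (3:151799492-151800263) fell from 113 ± 64.4 to 3.62 ± 5.13. MurSatRep1 in a coding exon of the zinc finger gene Zfp422 (6:116626508-116626876) fell from 50.3 ± 27.2 to 0.672 ± 1.502.

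B2 SINEs were higher in N2.1 than in F2. All 5 tested members rose (5 also adjusted over the list alone, 3 of 5 with TMM), with camera adjusted p = 0.00297 (adjusted p = 0.984 with an estimated correlation, 0.354 with TMM scaling). B2_Mm2 rose from 26749 ± 3362 to 38013 ± 1505 (log2 fold change 0.52, SE 0.07, adjusted p = 4.66e-06) and B2_Mm1t by 0.58 (SE 0.08, adjusted p = 5.92e-06). B2_Mm2 also differed between the library sets of the same Balb/c-2 tumours (37809 ± 1713 in the first, 29241 ± 1570.2 in the repeat set). Older L1 elements rose in 69 of 101 tested members with 0 lower (70 adjusted over the list alone, and 22 higher and 8 lower with TMM). Their camera adjusted p was 0.000294 (adjusted p = 0.984 with an estimated correlation, 0.0142 with TMM), and Lx8 rose by 0.39 (SE 0.07, adjusted p = 0.000175). Of young L1 elements 22 of 31 rose and 2 fell (25 adjusted over the list alone, and 7 and 3 with TMM). L1MdFanc_I had 0.71 (SE 0.23, adjusted p = 0.0161) and L1MdF_III -0.31 (SE 0.13, adjusted p = 0.0497). IAP had 6 of 24 members higher and 1 lower (4 adjusted over the list alone, and 2 and 2 with TMM). IAPEY4_I-int had 1.16 (SE 0.20, adjusted p = 6.07e-05) and IAP1-MM_I-int 0.64 (SE 0.09, adjusted p = 4.66e-06). ETn/MusD had 5 of 10 higher (5 adjusted over the list alone, and 3 higher and 1 lower with TMM), such as ETnERV2-int at 1.42 (SE 0.36, adjusted p = 0.00253). MMERVK10C had 4 of 14 higher and 1 lower (5 adjusted over the list alone, and 3 and 1 with TMM), with MMERVK10D3_I-int rising from 648 ± 174 to 2109 ± 904. VL30 had RLTR6B_Mm higher (0.81, SE 0.21) and MMVL30-int lower (-0.77, SE 0.31, adjusted p = 0.0457), 2 of 5 adjusted over the list alone. MMVL30-int had 45262 in F2 B and 13844 to 22714 in the other F2 libraries, and the groups overlapped (9494 to 27217 in N2.1). Of the 3 MuLV members RLTR4_Mm fell (-0.93, SE 0.26), 1 adjusted over the list alone.

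In other lists of N2.1 against F2 the counts of members depended on the scaling, since TMM moved the median log2 fold change of all subfamilies from 0.29 to 0.03. B1 SINEs had 12 of 15 members higher (13 adjusted over the list alone) with the deposited factors, but 5 lower and none higher with TMM, where camera gave the list as lower (adjusted p = 0.00159). MaLR had 43 higher and 4 lower of 122 (45 adjusted over the list alone) and with TMM 4 higher and 21 lower. DNA transposons had 47 and 12 of 204 (50 adjusted over the list alone) and with TMM 10 and 27. MERVL had 3 and 1 of 8 (5 adjusted over the list alone) and with TMM 0 and 4. B4 SINEs had 2 and 0 of 4 (3 adjusted over the list alone) and with TMM 0 and 3. MIR had 1 and 0 of 5 (1 adjusted over the list alone) and with TMM 0 and 3, and L2 3 and 0 of 6 (4) and with TMM 0 and 1. Satellites had 1 higher and 1 lower of 3 (2 adjusted over the list alone) and with TMM 0 and 1. Of the named subfamilies, LTR89B rose from 0.632 ± 1.41 to 11.8 ± 4.58. RLTR10D2, MER21-int, RMER16B, LTR107_Mam and RLTR9B2 rose by 1.54 to 2.40. MARE6 fell from 201 ± 48.5 to 72.7 ± 16.0, and UCON8 (-2.57), UCON14 (-1.43) and LTR91A (-0.97) fell.

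By limma 3222 loci passed in N2.1 against F2, 2439 higher and 783 lower, and 394 subfamilies, 360 higher and 34 lower. With TMM scaling 1392 loci were higher and 1325 lower, and 98 subfamilies higher and 130 lower. In all 132 subfamilies were called in the same direction under both scalings and 3 in opposite directions. Among intron copies 1055 were higher and 83 lower, and among 3' UTR copies 660 higher and 347 lower. The intron share was 24.8% ± 2.28 in N2.1 and 18.9% ± 4.32 in F2. With that share as a covariate 1147 loci and 127 subfamilies passed, and without F2 B 1919 loci. MER5C1 (1.85), Tigger17 (-1.90), LTR84a (-1.80), IAPEY5_I-int (-1.75) and UCON7 (-1.68) each lost their call without at least 3 of the 10 libraries in turn. Their adjusted p rose to 0.113, 0.129 and 0.0708 without F2 C for MER5C1, Tigger17 and UCON7, to 0.122 without F2 B for LTR84a and to 0.22 without N2.1 D for IAPEY5_I-int.

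N2.3 against N2.1 follows the N2 passages. RLTR20A4 in the 3' UTR of Igf2, the imprinted gene of insulin-like growth factor 2 (7:142652668-142652999), lay between 0 and 17.4 in N2.1 (n = 5). It rose to 333, 231 and 17104 in N2.3 A, B and C (log2 fold change 7.80, SE 1.014, adjusted p = 1.03e-05). An intergenic VL30 copy (4:143975533-143980475) rose from 50.7 ± 45.1 to 2498 ± 744 (6.41, SE 0.78, adjusted p = 2.79e-06) and had 491.5 to 3921 in N2.2. Of the 92 tested VL30 copies, 17 rose and 0 fell, while the subfamily MMVL30-int did not pass (1.16, SE 0.36, adjusted p = 0.0927). ORR1A2 in the 3' UTR of Lgr6, an R-spondin receptor gene (1:134984682-134985006), was 0 in N2.1 and 101 ± 139 in N2.3, at least 37.1-fold higher (7.55-fold without N2.3 C, which had 262 against 24.6 and 16.6 in A and B). Signal at this copy was not new in N2.3. It had 0, 8.67, 44.9 and 49.3 in F0 A, B, C and D, 17.9 in F1 E and at most 5.47 in F2. Lx6 (1:151240076-151243153), an intergenic L1 copy, rose from 4.43 ± 3.86 to 542 ± 699 (101, 177 and 1348 in N2.3 A, B and C). In F2 it had 13.7 to 166. MIR3 in the 5' UTR of Hspb8, a small heat shock protein gene (5:116422496-116422625), rose from 34.5 ± 37.4 to 713 ± 60.6. MuRRS-int in a coding exon of the zinc finger gene Zfp503 (14:21987495-21987585) fell from 173 ± 46.9 to 6.56 ± 11.4 (0, 0 and 19.7 in N2.3 A, B and C; -5.94, SE 0.52, adjusted p = 6.53e-10). It lay between 343 and 733 in the libraries of YUMM1.7 cells, F0, F1 and F2, and between 0 and 2.29 in the Balb/c and CBA libraries. On chromosome 1, MMERVK10C-int (1:44375644-44381206) fell from 27.7 ± 8.98 to 0.252 ± 0.437. Its neighbours L1MdA_III (1:44383129-44387713) and L1MdA_I (1:44368847-44375667) fell from 41.7 ± 18.1 to 1.09 ± 0.947 and from 29.7 ± 13.4 to 1.04 ± 1.15. MIRb in the 3' UTR of Mid2 (X:140765626-140765796) fell from 34.6 ± 32.1 (86.5 in N2.1 E) to 1.26 ± 2.19.

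Among subfamilies of N2.3 against N2.1, UCON88 rose from 15.1 ± 7.05 to 106 ± 65.8 (log2 fold change 2.69, SE 0.52, adjusted p = 0.0102). L1M4a1 rose by 0.50 and RLTR12D by 0.45, and both were lower over copies outside exons (-0.25 and -0.10). MMERGLN-int fell from 56219 ± 9189.8 to 30529.6 ± 7151 and MMAR1 from 255 ± 46.8 to 152 ± 28.2. Of the lists, older L1 had 1 member higher and DNA transposons 1 lower. Adjusted over the list alone young L1 and DNA transposons had 3, VL30 and MERVL 2, and IAP, MMERVK10C, MuLV and older L1 1. Intron shares were 23.8% ± 2.44 in N2.3 and 24.8% ± 2.28 in N2.1. By limma 466 loci (241 higher, 225 lower) and 5 subfamilies passed. Without N2.1 C, N2.1 E, N2.3 A or N2.3 B 222, 261, 268 or 223 loci passed, and without N2.1 A, B, C, D, E or N2.3 C 1, 15, 1, 0, 1 or 9 subfamilies. L1MdA_I lost its call without 1 of the 8 libraries and UCON88 without 2. The other 4 subfamilies and MIR3 in Hspb8 lost it without 5 or 6 of them in turn, with adjusted p up to 0.163 (MMERGLN-int without N2.3 C).

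**Figure D3:**
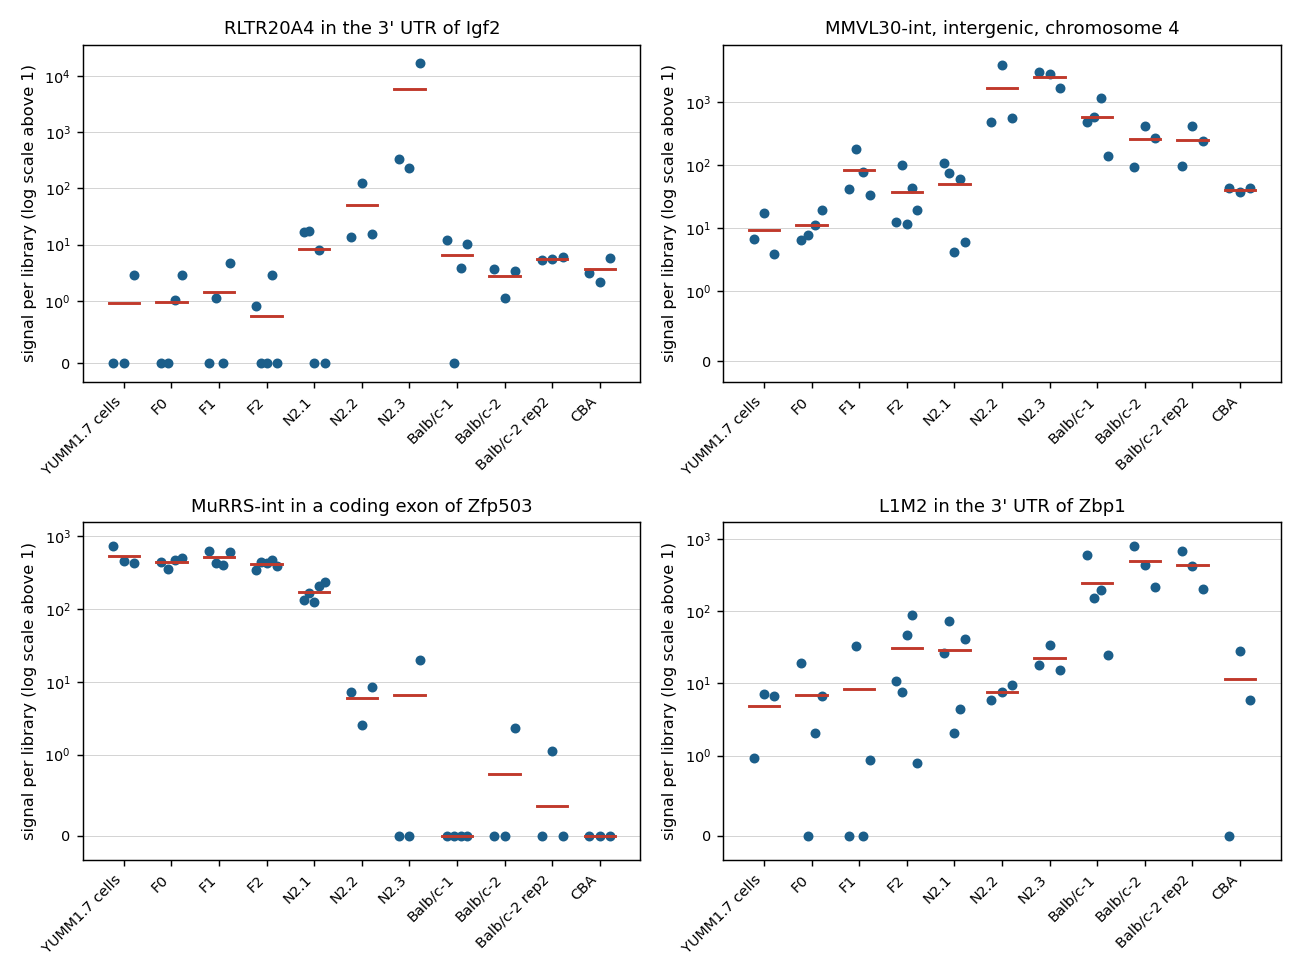
Signal per library (dots; log scale above 1, linear below) at RLTR20A4 in Igf2, an intergenic MMVL30-int copy of chromosome 4, MuRRS-int in Zfp503 and L1M2 in Zbp1 in the 11 groups, with the group mean (red line). MuRRS-int lay between 343 and 733 up to F2 and between 125 and 233 in N2.1.

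Balb/c-1 against N2.3 compares the first passage named for the Balb/c strain with the last N2 passage. The RLTR20A4 copy of Igf2, high in N2.3, fell to 6.56 ± 5.61 in Balb/c-1 (n = 4; log2 fold change -7.73, SE 1.06, adjusted p = 3.79e-05). In the 3' UTR of Lgr6, ORR1A2 fell from 101 ± 139 to 0.240 ± 0.480 and MER103C (1:134986304-134986546) from 69.0 ± 80.6 (162 in N2.3 C, 24.6 and 20.51 in A and B) to 0.781 ± 1.56. MMSAT4 in a coding exon of the transcription factor gene Egr2 (10:67540644-67540777) fell from 112 ± 19.2 to 3.49 ± 1.37. L1_Mur3 in the 5' UTR of P2ry14, a receptor gene for nucleotide sugars (3:59116228-59116343), rose from 0.252 ± 0.437 to 61.8 ± 32.9 (5.55, SE 0.94, adjusted p = 0.000891). B4A in the 3' UTR of the phosphatase gene Acpp (9:104289587-104289847) rose from 0.263 ± 0.456 to 49.7 ± 24.8, and an intergenic B3 (2:148805945-148806204) from 3.11 ± 5.38 to 55.5 ± 25.3. MERVL_2A-int in the 3' UTR of the cholinesterase gene Bche (3:73636117-73638340) rose from 3.59 ± 3.83 to 138 ± 151 (337 in Balb/c-1 A). ERVB2_1-I_MM in a coding exon of the interferon-inducible gene Ifi213 (1:173580639-173582295) rose from 0.526 ± 0.911 to 35.2 ± 34.7 (83.8 in Balb/c-1 A).

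In Balb/c-1 against N2.3, 12 of 92 VL30 copies fell and 0 rose, while the VL30 list did not pass (camera adjusted p = 0.194). RLTR6_Mm (-1.86, SE 0.41, adjusted p = 0.00618) and MMVL30-int (-1.29, SE 0.37, adjusted p = 0.0435) fell, 2 of 5 members of the list (2 adjusted over the list alone). With TMM MMVL30-int had adjusted p = 0.0617. Over copies in exons RLTR6_Mm was higher (0.02), as was MMVL30-int with compound names kept apart (0.25). MERVL-int fell by 0.69 on the log2 scale (SE 0.17, adjusted p = 0.0141), 1 of 8 members of its list (1 adjusted over the list alone). Young L1 elements rose in 2 of 31 members (2 adjusted over the list alone), L1MdFanc_I from 2576 ± 462 to 5513 ± 1614 and L1MdF_III from 5736 ± 1045 to 8984 ± 1249.8. The young L1 list had camera adjusted p = 0.0606 (0.0138 with TMM, and 0.0208 with 25 members when the case of names was kept). Older L1 had 3 of 101 lower (3 adjusted over the list alone) and DNA transposons 5 higher and 5 lower of 204 (16 adjusted over the list alone). B1 SINEs, MaLR (ORR1B1-int, 0.32) and IAP (IAP1-MM_I-int, 0.39) had 1 member higher each, also adjusted over the list alone, and with TMM B1 SINEs and IAP had 0. L2 and Satellites had 0 and, adjusted over the list alone, 1 each. Eulor10 (2.94), Charlie16a (0.96), Tigger6a (0.96), Kanga1 (0.88), BGLII_B2 (0.88) and MER74A (0.68) rose. Of these Charlie16a, Tigger6a, BGLII_B2 and MER74A were lower over copies outside exons (-0.32, -0.28, -0.02 and -0.07). MamGypLTR1d (-2.75), Charlie12_Rodent (-1.53), L3b (-1.43), MARE8 (-1.38), RLTR13B3 (-1.19) and RLTR13D4 (-1.12) fell.

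By limma 732 loci passed in Balb/c-1 against N2.3, 303 higher and 429 lower (438 and 291 with TMM), and 32 subfamilies, 15 higher and 17 lower. The intron share was 20.4% ± 2.86 in Balb/c-1 and 23.8% ± 2.44 in N2.3, and 46 intron copies were higher and 174 lower. Without N2.3 A, N2.3 B, N2.3 C, Balb/c-1 A or Balb/c-1 C 458, 487, 313, 358 or 375 loci passed, and without N2.3 A, N2.3 B, Balb/c-1 A or Balb/c-1 C 21, 18, 21 or 18 subfamilies. Of the 26 features taken by the rule 11 lost their call without at least 1 of the 7 libraries, MARE8 without 6 and L1MdFanc_I and MMVL30-int without 5. Without N2.3 C the adjusted p was 0.117 for BGLII_B2 and L1MdF_III, 0.128 for L1MdFanc_I, 0.138 for MARE8 and 0.206 for RLTR13D4. Without it the copies in Ifi213, Bche and Lgr6 (MER103C) had 0.0594, 0.156 and 0.076. Eulor10 and MMVL30-int had 0.0722 and 0.142 without N2.3 B, and RLTR6_Mm 0.0885 without N2.3 A.

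Balb/c-2 against Balb/c-1 compares successive Balb/c passages. MMVL30-int had 23613 ± 14604 in Balb/c-2 (n = 3) and 12498 ± 2571 in Balb/c-1 (n = 4; log2 fold change 0.77, SE 0.37, adjusted p = 0.357). The Balb/c-2 mean rests on tumour C (40297, against 17396 and 13147 in A and B). IAPEz-int had 7516 ± 2184 and 10158 ± 6606 (-0.30, SE 0.30, adjusted p = 0.68), and both differences lay within the spread between tumours. Young L1 summed to 56041 ± 3753 in Balb/c-2 and 52151 ± 6604 in Balb/c-1, and older L1 to 148071 ± 6968 and 136662 ± 10926. No member of any list was called over all subfamilies, and adjusted over the list alone MERVL had 2 and IAP, older L1 and B2 SINEs 1. By limma 0 loci and 0 subfamilies passed, with 3520 loci and 135 subfamilies at an unadjusted p under 0.05. edgeR called 0 of either, and DESeq2 66 loci and 8 subfamilies. With TMM 13 loci passed, and leaving out Balb/c-1 A, B, C or D gave 2, 33, 2 or 1 loci. Leaving out Balb/c-2 A, B or C gave 17, 130 or 8 loci, and leaving out Balb/c-1 B or Balb/c-2 B gave 14 or 1 subfamilies.

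CBA against Balb/c-2 rep2 compares the CBA passage with Balb/c-2 libraries of the same library set. The library name of Balb/c-2 rep2 B carries another run and lane code than those of the other libraries of both groups. Repeat copies of Zbp1, the interferon-inducible sensor of Z-form nucleic acids, fell. L1M2 in its 3' UTR (2:173206745-173207146) fell from 439 ± 244 in Balb/c-2 rep2 (n = 3) to 11.4 ± 14.9 in CBA (n = 3; log2 fold change -6.06, SE 1.23, adjusted p = 0.00272). ID_B1 in an intron of Zbp1 (2:173207281-173207474) fell from 95.7 ± 82.3 (181, 89.5 and 16.6 in A, B and C) to 0.362 ± 0.628. ERVB4_1-I_MM in an intron of AC132320.1 (18:60288796-60289913) fell from 154 ± 58.7 to 4.77 ± 6.33. B2_Mm2 in the 3' UTR of Soat2, a cholesterol esterification enzyme gene (15:102163279-102163468), fell from 117 ± 32.5 to 3.01 ± 2.61. An intergenic leukaemia virus type copy (RLTR4_MM-int, 10:5717715-5726008) fell from 107 ± 118 (242 in Balb/c-2 rep2 C, 54.6 and 23.2 in A and B) to 1.09 ± 1.05. ZP3AR in an intron of the DNA ligase gene Lig1 (7:13309816-13310333) rose from 1.11 ± 1.91 to 24.5 ± 7.26 (3.93, SE 0.65, adjusted p = 0.00047). RMER17C in a noncoding exon of the DNA glycosylase gene Neil3 (8:53590883-53593544) rose from 6.05 ± 8.27 to 52.4 ± 18.8. RMER6B in an intron of the centromere protein gene Cenpl (1:161074941-161075372) rose from 0.948 ± 0.826 to 21.7 ± 1.56. B1_Mus1 in an intron of the mitotic gene Cdc20 (4:118433956-118434098) rose from 0.444 ± 0.768 to 16.0 ± 5.48. L2c in an intron of the replication gene Gins1 (2:150913977-150914385) was 0 in Balb/c-2 rep2 and 13.9 ± 10.6 in CBA, at least 3.52-fold higher (2.01-fold without CBA C). The intron share was 25.9% ± 1.38 in CBA and 18.4% ± 0.949 in Balb/c-2 rep2 (exact permutation p = 0.1, the smallest that 3 against 3 can give).

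MMVL30-int had 8508 ± 309.9 in CBA against 23784 ± 15424 in Balb/c-2 rep2 (log2 fold change -1.30, SE 0.40, adjusted p = 0.0293). The latter mean rests on tumour C (41479, against 16689 and 13185 in A and B). Without C the log2 fold change was -0.80 (adjusted p = 0.236), and the call also ended without CBA A, B or C (adjusted p = 0.0771, 0.0620 and 0.0779). MMVL30-int was 1 of 5 VL30 members called (2 adjusted over the list alone), 10 of 92 VL30 copies fell and 1 rose, and the list did not pass (camera adjusted p = 0.655). RLTR4_MM-int rose from 7656 to 10329.6 (0.44, SE 0.14, adjusted p = 0.0322), 1 of 3 MuLV members (2 adjusted over the list alone, and 0 with TMM, adjusted p = 0.102). Young L1 had 2 of 31 higher and 5 lower (8 adjusted over the list alone), among the latter L1MdF_III (-0.56) and L1MdFanc_I (-0.94). Older L1 had 6 higher and 4 lower of 101 (9 adjusted over the list alone, and 5 and 12 with TMM). ETn/MusD had ETnERV2-int lower (-1.47, adjusted p = 0.0346), 1 of 10 members (1 adjusted over the list alone). IAP had 1 higher and 1 lower of 24 (0 adjusted over the list alone), the latter IAP1-MM_I-int (-0.34), and MMERVK10C 1 and 1 of 14 (2). MaLR had 10 higher and 9 lower of 122 (19 adjusted over the list alone, and 11 and 14 with TMM) and DNA transposons 9 and 18 of 204 (22). B2 SINEs had 1 and 1 of 5 (3 adjusted over the list alone), the latter B2_Mm1t (-0.41). L2 had 1 higher of 6 (2 adjusted over the list alone) and Satellites 1 lower of 3 (1). B1 SINEs had 2 of 15 higher (2 adjusted over the list alone), B1_Mm by 0.22, but 2 lower and none higher with TMM. MLTR32C_MM rose by 2.00 (-0.11 against the first Balb/c-2 library set), and L1MEg2, LTR107_Mam, MER67A, Tigger17b, MERV1_LTR, RLTR9D2 and L1M2c rose by 1.33 to 1.64. RLTR13D3 fell from 338 ± 147 to 31.4 ± 12.9, ERVB4_1-I_MM by 2.52 and MER89 by 2.01 on the log2 scale, although MER89 was higher over copies outside exons (0.50). LTRIS2, LTR67B, MER65-int, L1P5 and RLTR10F had -1.98 to -1.82.

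By limma 1970 loci passed in CBA against Balb/c-2 rep2, 1127 higher and 843 lower (887 and 1041 with TMM, and 1103 in all by edgeR), and 141 subfamilies, 69 higher and 72 lower. Of intron copies 629 were higher and 119 lower, while 176 3' UTR copies were higher and 438 lower. With the intron share as a covariate 252 loci and 60 subfamilies passed, and against the first Balb/c-2 library set 3601 loci, 1671 higher and 1930 lower. Without Balb/c-2 rep2 A, Balb/c-2 rep2 C, CBA A, CBA B or CBA C 1087, 631, 872, 1301 or 748 loci and 58, 60, 68, 75 or 66 subfamilies passed. The copies in Neil3 and AC132320.1 each lost their call without 1 library (adjusted p = 0.0508 without Balb/c-2 rep2 C and 0.0723 without CBA A). Of the 16 named subfamilies 10 lost their call without 2 or more of the 6 libraries in turn. LTR107_Mam lost it without each of the 6, MER67A, Tigger17b and L1M2c without 5 and MLTR32C_MM without 4. L1P5 and RLTR10F lost it without 3, and MERV1_LTR, MER89 and MER65-int without 2. The adjusted p rose to 0.232 (MLTR32C_MM without Balb/c-2 rep2 A).

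Libraries made again from the same Balb/c-2 tumours show how far library sets differ. With the tumour as a block, 153 loci passed by limma, 29 higher and 124 lower in Balb/c-2 rep2, and 217 subfamilies, 31 higher and 186 lower. B2_Mm2 had 29241 ± 1570.2 in Balb/c-2 rep2 (n = 3) and 37809 ± 1713 in Balb/c-2 (n = 3). B1_Mm had 16679 ± 157 and 18284 ± 749.6, and MMVL30-int 23784 ± 15424 and 23613 ± 14604. Without the block 1 locus passed, and without tumour A, B or C 0, 70 or 17.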

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

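All of the tests of explanations below were chosen after the results were seen; the counts of other splits followed a rule set beforehand but were written down afterwards. In 21 of the 171 groups checked 1 library lay far from the others of its group, and chance alone gives such a library in about 1 of 20 groups.

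Loci called in N2.1 against F2 were mostly higher in N2.1, 75.7% of 3222. With the intron share of each library as a covariate 1147 loci were called, 73.4% of them higher, while the median log2 fold change of all loci went from 0.26 to 0.04. The median of intron copies went from 0.43 to -0.035 and that of 3' UTR copies from 0.11 to 0.15, so the excess of intron copies ended. For the loci still called, which were mostly higher, this argues against more unspliced RNA in N2.1 as the whole cause. For the shift of the bulk of loci, and as a part of the cause, more unspliced RNA stays open. Over the 2439 higher loci the median log2 fold change went from 1.56 to 1.16 and over all called loci the median SE from 0.42 to 0.48, so calls ended through a smaller fold and a larger error. A single scaling factor per library would move introns and 3' UTRs alike; the difference between their medians was 0.316 larger in N2.1 (log2; exact two-sided permutation p = 0.183, n = 5 against 5), which leaves it open. With TMM, which centres the bulk of loci and so decides nothing here, 51.2% were higher. A sequencing or library batch cannot be told apart from the groups, because the labels do not assign libraries to batches. They also name a resequencing of the F2 cells without saying which run the F2 values come from, and 153 loci and 217 subfamilies (186 of them lower in the repeat set) differed between the library sets of the same Balb/c-2 tumours, and B2_Mm2 had 37809 ± 1713 in the first and 29241 ± 1570.2 in the repeat set. A change of repeat transcription between the passages stays open and was not tested.

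In N2.3 C whole chromosomes were shifted against N2.3 A and B, chromosome 15 by -0.58, chromosome 12 by -0.41, chromosome 16 by -0.33, chromosome 13 by -0.23 and chromosome 1 by 0.40 (median log2 of exon copies), and outside exons chromosome 15 by -0.49 and chromosome 1 by 0.41. A few strongly changed genes do not account for it, since 79.7% of the 251 exon copies of chromosome 15 lay below both other libraries and 10.8% above both. More unspliced RNA in N2.3 C is argued against by the correlation across the 20 chromosomes of these shifts with the slope on the intron share in other libraries (r = -0.0277; chromosomes are not independent replicates). A sample of another group cannot be told apart firmly: N2.3 C correlated across loci with N2.3 A and B at 0.157 and at most 0.109 with another group, N2.2. Relative to the median chromosome, N2.3 C lay beyond every other library on chromosomes 1 (0.442, others up to 0.182), 12 (-0.357, others down to -0.136), 13, 15 and 16. By smaller margins it also did so on chromosomes 4 (0.0887, others up to 0.0745), 5 (0.154, up to 0.109) and 7 (-0.141, down to -0.129). The same held on chromosomes 9 (0.137, up to 0.0833) and 17 (0.157, up to 0.1496). On chromosome 15 N2.3 C had -0.477, libraries up to N2.1 had -0.380 to 0.000786 and the others from N2.2 on 0.00285 to 0.476. A change in chromosome number may underlie the shifts and was not tested here.

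Host genes of the interferon response, measured at their exon repeat copies, were lower in CBA than in Balb/c-2 rep2 (median log2 fold change -3.08; camera adjusted p = 0.000246, and 0.524 with an estimated correlation). Of the 5 tested genes 4 were called and Ddx58 was not (adjusted p = 0.0837). Against the first Balb/c-2 set, which is of another library set than CBA, the median was -3.30 with 5 of 5 genes lower. Immune cells in the Balb/c-2 cultures could raise these genes; signal over the bodies of 6 immune marker genes was 5.53 ± 9.57 in Balb/c-2 rep2 and 2.87 ± 3.33 in CBA (n = 3 each). All of the former lay in Balb/c-2 rep2 B (16.6, with 0 in A and C), so the difference of 2.66 decides nothing. The strain of the host and the time in culture stay open as untested.

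Other libraries that lay far from their group were measured as follows. IAPEz-int had 20058 in Balb/c-1 A (others 6466 to 7082), and MMVL30-int had 45262 in F2 B (13844 to 22714). B1_Mm had 17811 in F0 B (16411 to 16534), and MMERGLN-int 40265 in N2.1 B (58088 to 63931). The RLTR4_MM-int copy of Camk2b had 188 in F0 C (65.9 to 85.9), and MER20 in Rasgrf1 had 131 in F2 E (28.7 to 53.7) and 1.68 in N2.1 A (others 0). RLTR45-int on chromosome 18 had 0.911 in F2 A, Lx8 in Itih5 2.52 and MurSatRep1 in Zfp422 3.36 in N2.1 A, LTR89B 3.16 in F2 C, ORR1A2 in Lgr6 0.961 in Balb/c-1 C and MER103C in Lgr6 3.12 in Balb/c-1 D, each with 0 in the other libraries of its group. These values, and that of MER20 in N2.1 A, rest on 1 to 4 reads, 1 for RLTR45-int and for ORR1A2, so they lie near counting error. In N2.1, UCON8 had 7.16 in B (others up to 1.68), Tigger17 11.8 in A (up to 3.12), UCON7 8.28 in E (1.77 to 3.36), UCON14 110.2 in C (32.7 to 48.2) and L1MdA_I on chromosome 1 53.0 in C (20.458 to 29.2). LTR91A had 50.3 in F2 B (24.6 to 27.4). Summed signal of interferon response host genes was 1762 in F1 B (220.5 to 406), and that of antigen presentation host genes 3817 in F2 D (998 to 1750.5).

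Other splits of the samples were counted for each result. For loci the groups called more than every other split counted in N2.1 against F2 (3222, highest other split 674, 1 of 100 splits as large, the real one included). The same held in Balb/c-1 against N2.3 (732 and 141, 1 of 35) and N2.3 against N2.1 (466 and 441, 1 of 56). In the last, the highest other split exchanges N2.3 C with N2.1 B, for a reason that was not tested. These shares were not adjusted over the results. In F2 against F0, 4 of 100 splits were as large as the 13 called, and the highest other split called 84. Chance is not excluded there, since other splits gave more calls and every named feature lost its call when single libraries were left out. In F0 against YUMM1.7 cells (0, highest other 81) and Balb/c-2 against Balb/c-1 (0 and 18) the groups called none. Every split is then as large, so the count decides nothing. Of the 35 splits, the groups included, 25 and 23 gave no call, and why the others gave calls was not tested. For subfamilies the groups called more than every other split counted in N2.1 against F2 (394 and 245, 1 of 100) and Balb/c-1 against N2.3 (32 and 19, 1 of 35). In N2.3 against N2.1 (5 and 19, 2 of 56) another split called more than the groups, for a reason that was not tested. Chance is not excluded there, nor in F2 against F0 (2 and 17, 5 of 100). In F0 against YUMM1.7 cells (0 and 7) and Balb/c-2 against Balb/c-1 (0 and 21) the groups called none, so the splits decide nothing. For called lists chance cannot be excluded in F0 against YUMM1.7 cells (1 and 2, 10 of 35) or N2.1 against F2 (2 and 3, 14 of 100). The splits are too few for a share under 0.05 in CBA against Balb/c-2 rep2 (1970 loci and 1 in the highest other of 10 splits, 141 subfamilies and 3) and in the repeat libraries of Balb/c-2 (153 and 0 of 4).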

How the results depend on the processing

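Alternatives of exons, intron share, chromosome Y, compound names, case of L1Md names and first library set were chosen after seeing the data, as was leaving out libraries for MMVL30-int in CBA, for folds against a group at 0 and for the host gene lists of F2. Of 102 features taken by the rule for named features, TMM kept the call and direction of 98, edgeR of 90, DESeq2 of 91, pseudocount 5 of 98, pseudocount 0.1 of 90, no filter of 94, an added minimum log2 fold change of 1 of 89, leaving out chromosome Y of 102, 2 groups alone of 75 and the intron share as a covariate of 60. Of simulated 2-fold changes at most 10.4% were called. How far the small number of changed loci, depth, group size or spread between tumours limits this was not tested. Where a count moved the cause was not tested, except that 2 groups alone and left-out libraries leave fewer samples.

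In the order F0 against YUMM1.7 cells, F2 against F0, N2.1 against F2, N2.3 against N2.1, Balb/c-1 against N2.3, Balb/c-2 against Balb/c-1 and CBA against Balb/c-2 rep2, no filter gave 3, 23, 1512, 2687, 2862, 1474 and 653 loci. Pseudocount 0.1 gave 15 (first comparison) and 41 (Balb/c-2), pseudocount 5 gave 7 (F2) and 13 (Balb/c-2) loci and 9 subfamilies (N2.3). A mean of at least 20 gave 27 (F2) and 1905 (N2.1) loci and 1 subfamily (F0). TMM gave 26 (F2) and 13 (Balb/c-2) loci and 1 (F0), 228 (N2.1) and 9 (N2.3) subfamilies. The 2 groups alone gave 0 (F2), 165 (N2.3), 133 (Balb/c-1) and 893 (CBA) loci and 1 (F2), 0 (N2.3) and 16 (Balb/c-1) subfamilies. The minimum log2 fold change of 1 gave 0 (F2), 56 (N2.1), 1 (N2.3), 11 (Balb/c-1) and 40 (CBA) subfamilies. edgeR gave 1 (F0), 3 (F2) and 1103 (CBA) loci and 25 (N2.3) and 49 (Balb/c-1) subfamilies. DESeq2 gave 7 (F0), 46 (F2), 742 (N2.3), 1197 (Balb/c-1) and 66 (Balb/c-2) loci and 1 (F0), 33 (N2.3), 77 (Balb/c-1) and 8 (Balb/c-2) subfamilies. Outside exons 4 (F2), 1422 (N2.1), 159 (N2.3), 254 (Balb/c-1), 6 (Balb/c-2) and 827 (CBA) loci and 0 (F2), 3 (N2.3), 4 (Balb/c-1) and 67 (CBA) subfamilies passed; in exons 1862 (N2.1), 292 (N2.3), 4 (Balb/c-2) and 1172 (CBA) loci and 153 (N2.1), 31 (N2.3), 92 (Balb/c-1) and 1 (Balb/c-2) subfamilies. The intron share as a covariate gave 1 (F0), 0 (F2), 1147 (N2.1), 404 (Balb/c-1), 22 (Balb/c-2) and 252 (CBA) loci and 0 (F2), 127 (N2.1), 21 (N2.3), 5 (Balb/c-2) and 60 (CBA) subfamilies. Compound names kept apart gave 4 (F2) and 26 (N2.3) subfamilies, and the first library set 3601 loci in CBA. Of 3 called lists, an estimated correlation left 0, and fry called 12, TMM 8, copies outside exons 19 and young L1 with case kept 4 (young L1 in Balb/c-1, adjusted p = 0.0208, was added).

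With the letter as a block, although letters do not pair these samples, 0 (F2), 1986 (N2.1), 64 (N2.3), 219 (Balb/c-1) and 142 (CBA) loci and 2 (N2.3) and 44 (CBA) subfamilies passed; without the block 1 locus passed between the library sets of the same tumours, against 153. The letter was not used as a block for F0 against YUMM1.7 cells, because titles number the cultures, although library names give them letters; no label links a culture to a tumour.

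Leaving out 1 library at a time gave, in the same order, 0 to 6, 0 to 48, 1919 to 3561, 222 to 696, 313 to 732, 1 to 130 and 631 to 2180 loci, 0 to 1, 0 to 4, 301 to 394, 0 to 15, 18 to 32, 0 to 14 and 58 to 134 subfamilies, and 0 to 70 loci between the library sets of the same tumours. Directions turned outside exons for MLTR18B_MM (-0.60, F2), L1M4a1 (-0.25) and RLTR12D (-0.10, both N2.3), Charlie16a (-0.32), Tigger6a (-0.28), BGLII_B2 (-0.0243) and MER74A (-0.06998, all Balb/c-1) and MER89 (0.50, CBA), and for B1 SINEs as a list (up, adjusted p = 0.00446, F0). They also turned for RLTR6_Mm in exons (0.0189) and MMVL30-int with compound names kept apart (0.25, both Balb/c-1), and for MLTR32C_MM against the first library set (-0.11, CBA).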

Other observations

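The tests of host genes, of single chromosomes and of the Wdr49 copies were chosen after the repeat results were seen, although the gene lists had been fixed before. At the exon repeat copies of 7513 host genes, limma called 1134 genes in N2.1 against F2 (716 higher, 418 lower), 299 in N2.3 against N2.1 (175 and 124), 543 in Balb/c-1 against N2.3 (270 and 273), 939 in CBA against Balb/c-2 rep2 (450 and 489), 13 in F2 against F0 (12 and 1), 2 in Balb/c-2 against Balb/c-1 and 1 in F0 against YUMM1.7 cells. Ifit1, an RNA-binding antiviral protein gene of the interferon response list, had 160.5 ± 149.7 in YUMM1.7 cells (n = 3), 179 ± 257 in F0 (n = 4), 223.6 ± 258 in F1 (n = 4), 447 ± 323 in F2 (n = 5), 796 ± 804 in N2.1 (n = 5), 276 ± 155 in N2.2 (n = 3), 543 ± 290 in N2.3 (n = 3), 2119 ± 1048 in Balb/c-1 (n = 4), 2585 ± 1293 in Balb/c-2 (n = 3), 1653 ± 776 in Balb/c-2 rep2 (n = 3) and 173 ± 178 in CBA (n = 3). In CBA against Balb/c-2 rep2, Isg15, a ubiquitin-like protein gene, fell by 4.09 on the log2 scale (SE 0.92, adjusted p = 0.00377), Ifit1 by 3.64 (SE 0.98, adjusted p = 0.0132) and the RNA sensor gene Ifih1 by 3.08 (SE 0.72, adjusted p = 0.00487), while Ddx58 had -1.74 (adjusted p = 0.0837); 4 of 5 tested members fell, 5 adjusted over the list alone (camera adjusted p = 0.000246; adjusted p = 0.524 with an estimated correlation). In Balb/c-1 against N2.3 the list did not pass (camera adjusted p = 0.0986) and 0 of 5 members were called, also adjusted over the list alone. The list was higher in F2 than in F0 (camera adjusted p = 0.00541; adjusted p = 0.524 with an estimated correlation), with 0 of 5 members called by limma and 3 adjusted over the list alone; without F0 B or F2 D it did not pass (camera adjusted p = 0.147 and 0.0642).

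Antigen presentation genes were higher in F2 than in F0 as a list (camera adjusted p = 0.0152; adjusted p = 0.524 with an estimated correlation), with 0 of 4 members called and 1 adjusted over the list alone. The summed signal of the list was 3817 in F2 D against 998 to 1750.5 in the other F2 libraries, and the list did not pass without F2 D, F2 A or F0 B (camera adjusted p = 0.0788, 0.0533 and 0.112). H2-D1, a class I histocompatibility gene whose reads were not separated from those of related genes, fell in CBA from 8731 ± 1323 to 2456 ± 1036 (log2 fold change -1.90, SE 0.43, adjusted p = 0.00369; -1.94 against the first Balb/c-2 set). Of 7 tested genes of repeat silencing, Uhrf1, which guides DNA methylation to replicated DNA, rose in N2.1 from 66.4 ± 31.7 to 166 ± 26.5 (1.42, SE 0.31, adjusted p = 0.00176) and in CBA from 24.8 ± 14.7 to 120.2 ± 21.1 (2.38, SE 0.40, adjusted p = 0.000301; 0.69 against the first Balb/c-2 set, which had 73.7 ± 8.34). The list passed in no comparison (smallest camera adjusted p = 0.196, for CBA). Pdgfra, the only tested fibroblast gene, fell in N2.1 from 721 ± 262 to 464 ± 399 (-0.86, SE 0.29, adjusted p = 0.0371). Of the melanocyte, immune and endothelial lists 2, 3 and 1 genes had an exon copy and none reached the mean needed for a test, and keratinocyte genes had 0 copies.

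IAPEz-int copies in an intron of Wdr49 (chromosome 3, 75348451 to 75353268) were high in single tumours. Their summed signal was 1441 in F1 B, 1010.5 in N2.1 E, 3801 in N2.2 A, 4736 in N2.2 C, 3808 in N2.3 A, 2165 in N2.3 B, 5646 in Balb/c-1 A and 1882 in Balb/c-2 A, with 2101 in the repeat library of that tumour, and it lay between 0 and 2.3 in the other Balb/c-2 tumours and between 0 and 2.1 in CBA. The 15 chromosome Y loci summed to 56.2 in F0 C against 228 to 416 in the other F0 libraries, and to 31.7 in CBA C against 390 and 429 in CBA A and B. Copies of chromosome 3 lay 0.32 higher in F2 (0.20 ± 0.13) than in F0 (-0.12 ± 0.04) relative to the median chromosome (exact two-sided permutation p = 0.0159, n = 5 against 4), which did not pass over 140 such tests, where the smallest adjusted p was 0.211. The smallest p that this permutation test can give with 5 against 4 is 0.00794. A single chromosome could therefore not pass over 140 tests, and the adjusted p decides nothing.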
